A study of Mus musculus with 8 samples.

How the data were processed

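Lung endothelial cells of female C57BL6 mice had been sorted as CD45-negative and CD31-positive cells, with 4 HF and 4 LF mice per the series' design text. Per the labels' protocols, RNA was isolated with TRIzol LS and libraries were made with a SMART-Seq kit, which amplifies full-length cDNA from small amounts of RNA. The submitters' processing notes name STAR 2.6.1b, featureCounts 2.0.0 and DESeq2 1.24.0, without an order. The genome build, the annotation and the strand setting of the counting are not given in the sources used here. The deposited table holds 34899 genes, none of them at 0 in every library.

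The authors deposited a normalised count per gene and library, a signal that is not scaled for gene length. Per the file headers, the same table holds the mean over libraries, a log2 fold change of HF over LF with its standard error, a Wald score, a p-value and an adjusted p-value from the authors' comparison. Each library's values were whole reads divided by a size factor of its own, between 0.820 and 1.27, so whole reads were recovered with a tolerance of 0.01 reads, and 100% of values came out whole. Library totals of recovered reads were 10631506 to 20781564. They limit the precision of genes with low counts, and reads amplified without molecular identifiers are not independent molecules. All 34899 gene IDs matched GENCODE M21 (GRCm38), which supplied positions, exon lengths, GC content and overlaps. Of the deposited symbols, 24 had been turned into dates and were restored from that annotation. Columns were matched to samples by their labels, and 0 columns of per-sample values matched no sample.

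Genes with at least 10 normalised counts in at least 4 libraries were tested, 17067 in all. The main test was limma's moderated test with a mean-variance trend on log2(normalised count + 1), two-sided, without covariates, with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. It was chosen before the data were examined, since the values were expected to be normalised counts, and edgeR's quasi-likelihood test with TMM and DESeq2 were run on the recovered reads as alternatives. Folds and their 95% intervals come from the limma fit, whose moderated test had 12.3 degrees of freedom. They understate the change of genes with low counts.

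Gene lists numbered 48 and were written before the data were examined, for endothelial functions, metabolism, stress, RNA quality, endothelial subtypes and other cell types, with 1104 genes, of which 7 had no row in the deposited table. They were tested with camera from limma at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation called 0 of the 48 lists and fry's directional test called 0, where the preset correlation called 27, 13 higher and 14 lower in HF. The smallest adjusted p was 0.192 with an estimated correlation and 0.144 with fry. On the data, both were run only with all 8 libraries, so list calls in the other fits rest on the preset correlation. Fry's test for change in either direction (mixed) called 9. No member of any list passed limma over all genes tested (0 of 17067 genes, with 1882 at an unadjusted p under 0.05, 0 by edgeR and 326 by DESeq2). A list's score in a library is the mean log2 deviation of its genes, compared by an exact permutation test over the groups of 4 against 4.

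The genes named in the text followed a rule fixed before the data were examined. It took up to 12 genes per direction with the largest change among those that passed the threshold with groups that do not overlap and, with fewer than these, the genes with the smallest unadjusted p up to 8 per direction. As none passed, all came from the second part, of which 15 genes are given and 1 is not reported here, with a higher group mean of at least 50 and a symbol that is no clone, accession or pseudogene name. Up to 4 members with the smallest p were named per list, and 19 genes for the sorted cells, other cells, adhesion, junctions and oxidative stress were always given.

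No pair of libraries agreed within sampling noise, since the chi-square per degree of freedom over genes lay between 9.96 and 50.7, so all 8 were counted as samples. Alternatives planned in advance were other count models, pseudocounts of 0.5 and 5, no filter, a mean of at least 50, quantile normalisation, TMM rescaling, array weights, robust variance moderation, the replicate number as a block, leaving out each library and a threshold of 0.10. Added after the data were seen were leaving out pairs of LF libraries, 1 surrogate variable, thinning of reads to the lowest library, and regression on GC content and exon length. The overlap of calls between the fits that leave out a pair of LF libraries was set beside 20 simulations of unchanged groups with the same HF libraries in both fits, and was also chosen after the data were seen.

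The tests were tried on simulated counts with the means, dispersions and library sizes of the HF against LF comparison, on 17067 genes with 200 changed by known folds. These 200 were drawn from genes with a mean of at least 50, so recovery at lower counts was not tried. limma recovered 23.9%, 76.1% and 95.5% of genes changed by folds of 1.5, 2 and 4, edgeR 22.4%, 77.6% and 98.5%, and DESeq2 52.2%, 88.1% and 98.5%, with 2, 5 and 27 false calls. In a simulation with nothing changed, DESeq2 made 5 calls, and limma and edgeR made 0. Genes were simulated independently, so these counts do not cover structure among the real libraries. Of 2 simulated lists of 30 genes shifted by 0.4 on the log2 scale, camera called 2, and 1 with an estimated correlation. R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, sva 3.50.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.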

Results

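RNA-seq was performed on lung endothelial cells of female C57BL6 mice, sorted by flow cytometry as cells without CD45, the surface marker shared by leukocytes, and with CD31, the adhesion molecule of endothelium encoded by Pecam1. There were 4 libraries from HF and 4 from LF mice. The labels name these groups without spelling them out, and the series title places them in a study of obesity, neutrophil oxidants, vascular inflammation and the passage of tumour cells across the vessel wall. The comparison asks how transcript levels in the lung endothelium of HF mice differed from those of LF mice. Libraries held between 10631506 reads assigned to genes (LF 1) and 20781564 (HF 4). Values are the authors' normalised read counts, given as mean ± SD with n = 4 per group, and folds are HF over LF on the log2(value + 1) scale with 95% intervals. Pecam1 was at 28252 ± 1063 in HF and 25381 ± 6906 in LF, and Cdh5, the endothelial cadherin of adherens junctions, at 13037 ± 196 and 11154 ± 1655. Ptprc, which encodes CD45, was at 166 ± 72.8 and 199 ± 59.0.

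The genes that separated the groups most clearly included secreted signals and a regulator of lipid uptake. Inhbb (ENSMUSG00000037035), which encodes a subunit of activins and inhibins, was at 283 ± 74.7 in HF and 81.3 ± 26.1 in LF, a log2 fold change of 1.81 (fold interval 2.41 to 5.07). Angptl4 (ENSMUSG00000002289), a secreted inhibitor of lipoprotein lipase, was at 304 ± 58.0 against 120.2 ± 29.1, a fold of 2.53 (1.85 to 3.48). Dhh, the ligand desert hedgehog, was at 265 ± 29.8 against 124 ± 26.6, a fold of 2.16 (1.63 to 2.85). The folds were 1.80 for Galnt10, a glycosyltransferase that starts mucin-type O-glycans, 1.78 for Slc26a10, 1.72 for Tmem221, 1.70 for Adpgk, the ADP-dependent glucokinase, and 1.60 for Ppp1cc, a catalytic subunit of protein phosphatase 1.

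On the lower side, Wnt5a, a secreted Wnt ligand, was at 37.2 ± 5.19 in HF and 93.9 ± 13.5 in LF, a fold of 0.403 (0.288 to 0.563). Scgb3a2, a secretoglobin of airway epithelium, was at 186 ± 47.99 against 456 ± 143.4, a fold of 0.419 (0.287 to 0.612). Carmn, a long noncoding RNA of smooth muscle, had a fold of 0.471. The neighbouring paralogs Lilr4b and Lilrb4a, receptors of the leukocyte immunoglobulin-like family, had folds of 0.507 and 0.564, and both overlap the gene model Gm49339 on their own strand. Ifitm1, an interferon-induced membrane protein, was at 490.2 ± 22.4 against 820.1 ± 107, a fold of 0.601, and Rflna had a fold of 0.563. In each of these 15 genes the 4 HF values lay entirely above or entirely below the 4 LF values.

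**Figure D1:**
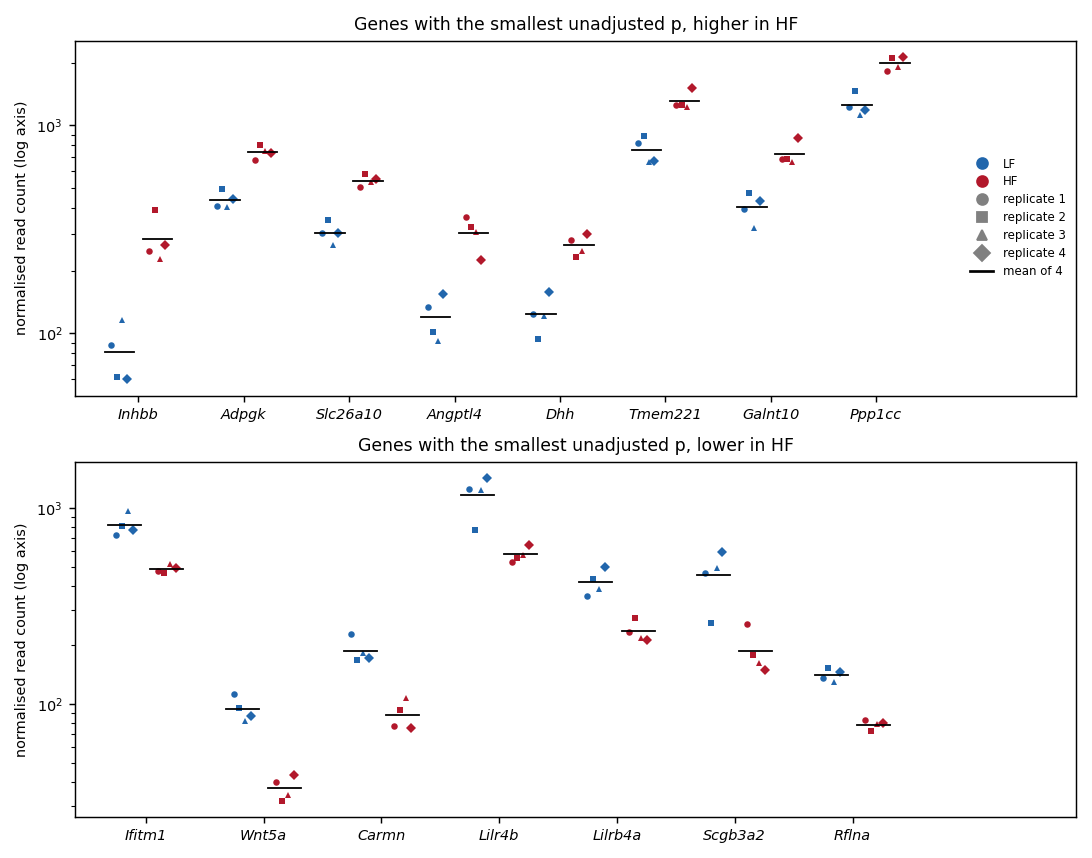
Normalised read counts on a log axis for the 15 genes above, 8 higher and 7 lower in HF, with points for single libraries (LF blue, HF red, shape by replicate) and bars for means of 4. In all 15 genes the HF points lie on the opposite side of every LF point, for example Inhbb at 227 to 393 in HF and 59.9 to 115 in LF.

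None of these genes passed the main test, since limma called 0 of 17067 genes at a Benjamini-Hochberg adjusted p under 0.05, with adjusted p values of 0.124 to 0.162 for the 15 named genes. At an unadjusted p under 0.05, limma gave 1882 genes, 1085 higher and 797 lower in HF, where 853 are expected by chance. edgeR's quasi-likelihood test on the recovered reads also called 0 genes, with 1905 at an unadjusted p under 0.05. DESeq2 on the same reads called 326, of which 253 were higher and 73 lower. The authors' deposited table lists 311 genes at an adjusted p under 0.05 by DESeq2, 241 higher and 70 lower in HF, among 15276 genes with an adjusted p. All of those 311 genes of the authors' deposited table had an unadjusted p under 0.05 and the same sign in the limma fit, with limma adjusted p values from 0.124 to 0.340. The groups did not overlap in 927 genes, 592 with HF above LF and 335 with HF below, which is 5.43% of the genes tested. For a single gene without a group difference, the probability is 2.86%. That figure takes no account of structure among the libraries, and the count was not made for other splits of the libraries. Chance was therefore not excluded for this count. Several named genes overlap others in the GENCODE M21 annotation of GRCm38: Adpgk overlaps Bbs4, Slc26a10 overlaps B4galnt1 and Wnt5a overlaps Gm2670 on the other strand, and Dhh overlaps Rhebl1 on its own strand. Whether counting used strand is not given in the sources used here. In that annotation Inhbb lies on chromosome 1 from 119415465 to 119422248, Angptl4 on chromosome 17 from 33773750 to 33781830, and Lilr4b on chromosome 10 from 51480632 to 51486703.

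The LF libraries were not alike. LF 1 and LF 2 stood apart on the first principal component, at -56.4 and -50.9, while the other 6 libraries lay between -6.79 and 39.6, and LF 3 and LF 4 lay at -38.5 and -34.2 on the second. LF 1 and LF 2 also had 0.725% and 0.635% of reads in genes of the GENCODE biotype TEC, against 0.286% to 0.443% in the other libraries. The HF libraries were spread on the first component as well, with HF 1 and HF 3 at -6.79 and 3.26 and HF 2 and HF 4 at 31.7 and 39.6. Leaving out an LF pair keeps all 4 HF libraries, so it does not balance that spread. With LF 1 and LF 2 left out, limma called 641 genes at an adjusted p under 0.05, 528 higher and 113 lower. With LF 3 and LF 4 left out it called 3421, with 2393 genes higher in HF and 1028 genes lower in HF. These fits share the HF libraries. Both called 118 genes in the same direction and 40 in opposite directions, where independent lists of these sizes would share 80.8 and 47.6. In 20 simulations with nothing changed, at most 1 gene was called by both. These simulations gave every library the same gene means, without the difference between the LF pairs. They therefore set no level for the shared calls here. With separate pairs of HF libraries in each fit, in 6 ways, 4 to 77 genes were shared in the same direction and 1 to 32 in opposite directions. Those fits called 24 to 899 genes without LF 1 and LF 2 and 284 to 4455 without LF 3 and LF 4. What independent lists of those sizes would share was not computed. Of the 15 named genes, picked for the smallest p with all 8 libraries, 14 passed limma's adjusted threshold without LF 1 and LF 2, with Rflna at an adjusted p of 0.0648, and all 15 passed it without LF 3 and LF 4.

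**Figure D2:**
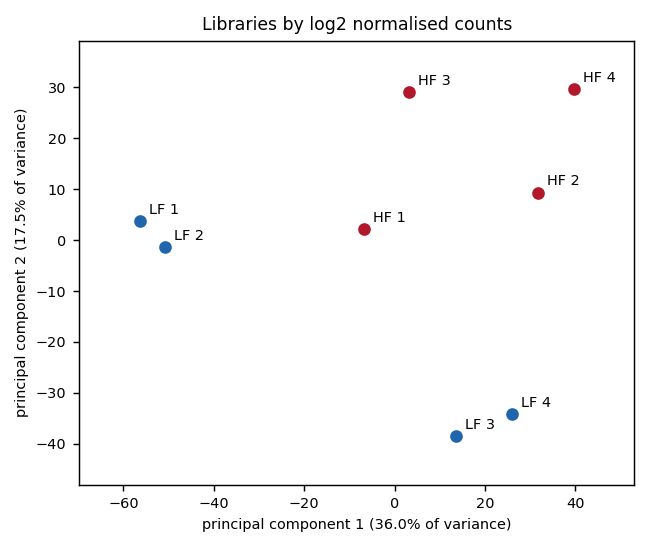
First against second principal component of the log2 normalised counts of the 17067 genes tested, with 1 point per library (HF red, LF blue). LF 1 and LF 2 lie at -56.4 and -50.9 on the first component, and LF 3 and LF 4 at -38.5 and -34.2 on the second.

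The lists for leukocyte adhesion, cell junctions and oxidant defence, which the series title brings into question, were not called with all 8 libraries. Icam1, the ligand of leukocyte integrins, was at 9315 ± 805 in HF and 10696 ± 2670 in LF, a fold of 0.890 (0.681 to 1.16). Its log2 fold change was -0.47 without LF 1 and LF 2 (limma adjusted p = 0.0334) and 0.13 without LF 3 and LF 4 (limma adjusted p = 0.439). Vcam1 had a fold of 0.889 (0.692 to 1.14), P-selectin (Selp) 0.949 (0.655 to 1.37) and E-selectin (Sele) 1.09 (0.592 to 2.02). Among 23 measured members of the adhesion and transmigration list, 12 had the higher mean in HF, and the list was not called by limma's camera (adjusted p = 0.521). Its median log2 fold change was 0.08, while its mean of -0.11 and the direction of the test were lower in HF. The list was lower in HF without LF 1 and LF 2 (median -0.24, camera adjusted p = 4.21e-05) and higher without LF 3 and LF 4 (median 0.35, camera adjusted p = 0.0241).

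Of the 30 junction genes, 23 had the higher mean in HF, with a median log2 fold change of 0.17 (camera adjusted p = 0.0619). The junction median was -0.042 without LF 1 and LF 2 (camera adjusted p = 0.926) and 0.24 without LF 3 and LF 4 (camera adjusted p = 0.00118). Camera called the list higher with the replicate block (adjusted p = 0.0439). Gap junction genes had the smallest p in this list, with Gjc1 at 1219.5 ± 183 against 826 ± 144 and Gja5, whose groups did not overlap, at 919.5 ± 36.9 against 597 ± 166. Cldn5, Ocln and Tjp1, the claudin, occludin and scaffold of tight junctions, had folds of 1.16 (0.870 to 1.55), 1.21 (0.936 to 1.56) and 1.04 (0.854 to 1.27). For oxidant defence, 27 of 42 genes had the higher mean in HF (median 0.09, camera adjusted p = 0.416). The median was -0.099 without LF 1 and LF 2 (camera adjusted p = 0.230) and 0.27 without LF 3 and LF 4 (camera adjusted p = 0.0370). Catalase (Cat) had a fold of 1.15 (0.890 to 1.47), Sod2, the mitochondrial superoxide dismutase, 1.06 (0.847 to 1.33) and the heme oxygenase Hmox1 1.06 (0.807 to 1.40), while glutathione reductase (Gsr) was at 1.47 and the extracellular enzymes Gpx3 and Sod3 at 0.745 and 0.632. Every HF value lay below every LF value for Gpx3 and for the glutathione transferase Gsta4 (0.532). Without LF 3 and LF 4, limma called Cldn5, Ocln, Cat and Sod2 higher in HF (adjusted p = 0.00845, 0.0172, 0.0134 and 0.0454). Without LF 1 and LF 2 it called none of these, with log2 fold changes of -0.11, -0.0077, -0.11 and -0.18. In the list of oxidant producers, 6 of 18 genes had the higher mean in HF (median -0.31, camera adjusted p = 0.262). Its member Rac1, a small GTPase with many roles besides the NADPH oxidase, was at 7426 ± 2903 in HF and 3049.9 ± 1154 in LF. Nos3, the endothelial nitric oxide synthase, was at 1259 ± 83.9 against 938 ± 268, a fold of 1.38 (1.06 to 1.79) with a limma adjusted p of 0.352, and it overlaps Atg9b on the other strand. Its log2 fold change was 0.18 without LF 1 and LF 2 (limma adjusted p = 0.675) and 0.75 without LF 3 and LF 4 (limma adjusted p = 0.00464).

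Genes of lipid uptake and fatty acid handling were higher in HF as a list. Of 43 measured members, 37 had the higher mean in HF, the median log2 fold change was 0.30, and camera called the list (adjusted p = 8.97e-08; adjusted p = 0.470 with an estimated correlation). Beside Angptl4, the leading members were Cpt1a, which commits long-chain fatty acids to mitochondrial oxidation, at 5231 ± 419 in HF and 3041 ± 912 in LF (1.78-fold), the hormone-sensitive lipase Lipe at 2250.0 ± 89.4 against 1264 ± 535 (1.89-fold), and the mitochondrial carrier Ucp2 at 7621 ± 935 against 4789.8 ± 1196 (1.62-fold). Adjusted over the list alone, 6 of the 43 genes passed limma's threshold, all higher. The list's score per library was above that of every LF library in all 4 HF libraries (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 allows; adjusted p = 0.305 over the 48 lists by Benjamini-Hochberg). The median was 0.20 without LF 1 and LF 2 and 0.44 without LF 3 and LF 4, and camera called the list in both (adjusted p = 0.00679 and 1.62e-07).

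The lists for nitric oxide and vasoactive signalling and for angiogenesis were also called higher in HF. Their medians were no larger than that of markers shared by all endothelium (0.22), and 16 of 36 and 17 of 37 members stand in other lists too, as do 16 of the 18 shared markers. The nitric oxide and vasoactive list had 29 of 36 members with the higher mean in HF (median 0.19, camera adjusted p = 0.00503; adjusted p = 0.498 with an estimated correlation). Its examples were Ddah1, which degrades inhibitors of nitric oxide synthase, at 1.43-fold, the vasoconstrictor endothelin (Edn1) at 1.43-fold, Bmp6 at 1.75-fold and the flow-responsive factor Klf2 at 2.16-fold. Adjusted over the list alone, limma called 5 of its genes higher and Gucy1a1, also a pericyte marker, lower. The angiogenesis list had 29 of 37 members with the higher mean in HF (median 0.17, camera adjusted p = 0.00709; adjusted p = 0.470 with an estimated correlation). Its members with the smallest p were the Notch receptor Notch4 at 3694 ± 1144 against 1729 ± 718 (2.21-fold), the Notch ligand Jag1 at 828 ± 142.7 against 548 ± 47.8, the arterial transcription factor Sox17 at 1.91-fold and the diaphragm protein Plvap at 1.64-fold. Both calls were lost without LF 1 and LF 2, where the medians were -0.037 and -0.0038 (camera adjusted p = 0.761 and 0.1395). They were also lost with quantile normalisation (camera adjusted p = 0.0767 and 0.2005) and with 1 surrogate variable (camera adjusted p = 0.1802 and 0.0562).

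Marker lists of endothelial subtypes were also higher in HF. Arterial markers were higher in 16 of 17 genes (median 0.19, camera adjusted p = 9.43e-04; adjusted p = 0.470 with an estimated correlation), with Gja5 at 1.59-fold and Vegfc at 1.49-fold, and Mgp, a matrix protein, at 0.718. General capillary markers were higher in 14 of 16 genes (median 0.22, camera adjusted p = 3.75e-04; adjusted p = 0.470 with an estimated correlation), with lipoprotein lipase (Lpl) at 1.39-fold and Sema3c at 1.33-fold. Of the arterial and general capillary members, 9 of 17 and 9 of 16 stand in other lists too, Lpl among them in fatty acid handling. Markers shared by all endothelium were higher in 17 of 18 genes (median 0.22, camera adjusted p = 0.00650; adjusted p = 0.592 with an estimated correlation). Venous markers were higher in 11 of 16 (median 0.18, camera adjusted p = 0.0376; adjusted p = 0.502 with an estimated correlation). Aerocyte markers (median 0.09, camera adjusted p = 0.521) and lymphatic markers (median -0.16, camera adjusted p = 0.546) were not called. Aerocyte markers were lower in HF without LF 1 and LF 2 (median -0.28, camera adjusted p = 2.41e-04) and with 1 surrogate variable (camera adjusted p = 0.00133), and higher without LF 3 and LF 4 (median 0.42, camera adjusted p = 4.18e-04). Without LF 1 and LF 2 the arterial and venous calls were kept (medians 0.20 and 0.063), while the general capillary call was lost (camera adjusted p = 0.0577) and the shared endothelial markers had a median of -0.052 (camera adjusted p = 0.608). The venous call was lost without LF 3 and LF 4 (camera adjusted p = 0.125), with thinned reads (0.0586), with GC content and exon length regressed out (0.113) and with quantile normalisation (0.0788). The shared endothelial call was also lost with quantile normalisation (median 0.089, camera adjusted p = 0.0507) and with 1 surrogate variable (median 0.024, camera adjusted p = 0.437).

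Lists for the unfolded protein response, immediate early genes, hypoxia, insulin response, apoptosis and oxidative phosphorylation were called higher too. Heat shock was not (median 0.13, camera adjusted p = 0.107). The unfolded protein response had 25 of 28 members with the higher mean in HF (median 0.24, camera adjusted p = 5.30e-04; adjusted p = 0.569 with an estimated correlation), with Edem1, a lectin of protein quality control, at 1.45-fold and the sensor kinase Eif2ak3 at 1.64-fold. Immediate early genes, which cell dissociation also induces, were higher in 24 of 28 genes (median 0.22, camera adjusted p = 2.34e-04; adjusted p = 0.470 with an estimated correlation), with Rhob at 1.55-fold and Dusp1 at 1.48-fold. Hypoxia genes (17 of 23, median 0.21) were called by camera with adjusted p = 0.0195 (adjusted p = 0.502 with an estimated correlation). Of the hypoxia and immediate early genes, 9 of 23 and 11 of 28 stand in other lists too, with Angptl4 also in fatty acid handling. Insulin and glucocorticoid response genes (18 of 27, median 0.17) had adjusted p = 0.0336 by camera (adjusted p = 0.497 with an estimated correlation), with Irs2, an insulin receptor substrate, lower at 0.598. Apoptosis and p53 targets (20 of 27, median 0.13) had adjusted p = 0.0376 by camera (adjusted p = 0.569 with an estimated correlation). Nuclear genes of oxidative phosphorylation (46 of 54, median 0.09) had adjusted p = 0.0420 by camera (adjusted p = 0.813 with an estimated correlation). In the fit without LF 1 and LF 2, camera kept its calls for immediate early genes (median 0.095) and insulin response (median 0.16). It lost there those for unfolded protein response, hypoxia and apoptosis (medians -0.0995, -0.096 and -0.021). In the same fit camera called oxidative phosphorylation lower in HF (median -0.12, adjusted p = 3.40e-05). The insulin response call was lost without LF 3 and LF 4 (median 0.08, camera adjusted p = 0.366), with thinned reads (camera adjusted p = 0.0574), with GC content and exon length regressed out (camera adjusted p = 0.102) and with quantile normalisation (camera adjusted p = 0.171). The apoptosis call was also lost with thinning, that regression and quantile normalisation (camera adjusted p = 0.0574, 0.116 and 0.538). Thinning and quantile normalisation ended the oxidative phosphorylation call (camera adjusted p = 0.0574 and 0.567), and quantile normalisation the hypoxia call (camera adjusted p = 0.188). Adding 1 surrogate variable ended the calls for unfolded protein response, hypoxia, apoptosis and oxidative phosphorylation (medians 0.013, 0.024, 0.048 and -0.049, camera adjusted p = 0.582, 0.355, 0.290 and 0.0698). Heat shock was called lower without LF 1 and LF 2 (median -0.16, camera adjusted p = 0.00400) and higher without LF 3 and LF 4 (median 0.53, camera adjusted p = 8.17e-06) and with the replicate block (camera adjusted p = 0.0439).

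**Figure D3:**
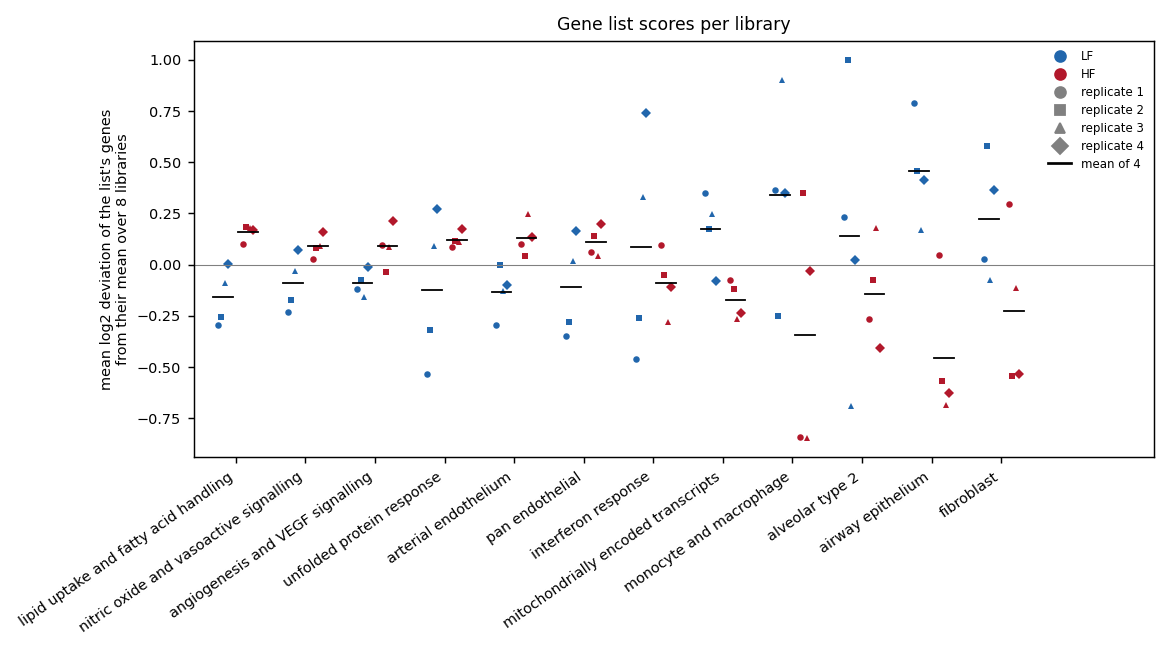
Score of 12 gene lists in each library, on a vertical axis of the mean log2 deviation of a list's genes from their means over the 8 libraries, with points for libraries (LF blue, HF red) and bars for means of 4. Fatty acid handling scores lie between 0.101 and 0.184 in HF and between -0.292 and 0.0043 in LF, whereas the LF interferon scores spread from -0.459 to 0.741.

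Transcripts of other cell types were lower in HF, in 10 of 13 such lists by camera. All 15 airway epithelium markers had the lower mean in HF (median -0.79, camera adjusted p = 1.15e-08; adjusted p = 0.192 with an estimated correlation), with the antimicrobial lectin Reg3g at 78.5 ± 57.6 against 208 ± 69.2 and the secretoglobin Scgb3a1 at 291 ± 138 against 690 ± 213. The exact two-sided permutation p of its score was 0.0286 (adjusted p = 0.305 over the 48 lists by Benjamini-Hochberg). For every other one of these 10 lists that p was between 0.0857 (neutrophil) and 0.486 (alveolar type 2), so their scores overlapped between the groups. Monocyte and macrophage markers were lower in 22 of 23 genes (median -0.64, camera adjusted p = 8.97e-08; adjusted p = 0.470 with an estimated correlation), with Chil3 at 521 ± 298 against 1080 ± 381. Neutrophil markers were lower in all 12 genes (median -0.85, camera adjusted p = 2.80e-04; adjusted p = 0.470 with an estimated correlation), with S100a8 at 50.6 ± 28.2 against 89.9 ± 47.1. Lymphocyte markers were lower in 15 of 16 (median -0.67, camera adjusted p = 5.32e-05; adjusted p = 0.470 with an estimated correlation). Erythrocyte markers were lower in all 10 (median -0.44, camera adjusted p = 8.62e-05; adjusted p = 0.470 with an estimated correlation), with Hbb-bs at 8738 ± 554 against 12004 ± 3617. The erythrocyte median was -0.057 without LF 3 and LF 4 (camera adjusted p = 0.532) and -0.85 without LF 1 and LF 2 (camera adjusted p = 1.15e-14).

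Stromal and alveolar markers followed. Fibroblast markers were lower in 21 of 22 genes (median -0.48, camera adjusted p = 1.60e-07; adjusted p = 0.470 with an estimated correlation), with Col3a1 at 509 ± 205 against 901 ± 329 and Col1a1 at 163 ± 79.1 against 239.6 ± 89.6. Pericyte and smooth muscle markers were lower in 16 of 20 (median -0.34, camera adjusted p = 4.89e-06; adjusted p = 0.470 with an estimated correlation), mesothelial markers in 7 of 8 (median -0.49, camera adjusted p = 9.43e-04; adjusted p = 0.470 with an estimated correlation) and alveolar type 1 markers in 12 of 16 (median -0.28, camera adjusted p = 0.0146; adjusted p = 0.470 with an estimated correlation). Alveolar type 2 markers were lower in 13 of 17 (median -0.21, camera adjusted p = 0.0195; adjusted p = 0.651 with an estimated correlation), with the surfactant gene Sftpc at 5805 ± 1600.4 against 6628 ± 3020.0. Platelet markers were not called (median 0.26, camera adjusted p = 0.336), with Pf4 at 529.7 ± 391 against 380.2 ± 172. Without LF 1 and LF 2, 7 of the 10 calls were kept. Those lost were alveolar type 2 (median 0.19, camera adjusted p = 0.242), alveolar type 1 (median -0.083, camera adjusted p = 0.497) and mesothelial markers (median -0.42, camera adjusted p = 0.235). LF 2 had the highest score of the 8 libraries in each of these lists (1.001, 0.654 and 0.812). Without LF 3 and LF 4, 9 of the 10 were kept, all but the erythrocyte call. With 1 surrogate variable the alveolar type 2, alveolar type 1 and mesothelial calls were lost (medians 0.0082, -0.16 and -0.40, camera adjusted p = 0.669, 0.0774 and 0.0531).

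Mitochondrially encoded transcripts were lower in HF in all 15 genes (median -0.34, camera adjusted p = 1.59e-08; adjusted p = 0.470 with an estimated correlation), with mt-Co3 at 730 ± 66.1 against 978 ± 109. They took 0.672% ± 0.033 of the reads in HF and 0.935% ± 0.161 in LF (exact two-sided permutation p = 0.0286; adjusted p = 0.171 over 9 library measures). With GC content and exon length regressed out, the median of the mitochondrially encoded list was -0.11 (camera adjusted p = 0.0249). Cytoplasmic ribosomal protein genes were lower in 46 of 52 (median -0.097, camera adjusted p = 0.00332; adjusted p = 0.743 with an estimated correlation), and nuclear retained RNAs in 5 of 6 (median -0.30, camera adjusted p = 0.0376; adjusted p = 0.470 with an estimated correlation). Both calls were lost with that regression (medians -0.033 and -0.18, camera adjusted p = 0.0680 and 0.292). The ribosomal call was also lost without LF 3 and LF 4 (median -0.037, camera adjusted p = 0.417), and the nuclear retained call without LF 1 and LF 2 (median -0.026, camera adjusted p = 0.724). Adding 1 surrogate variable ended the nuclear retained call too (median -0.12, camera adjusted p = 0.313). Interferon response genes were lower in 29 of 39 (median -0.11, camera adjusted p = 0.0147; adjusted p = 0.803 with an estimated correlation), with the GTPase Iigp1 at 11285 ± 1827 against 16565 ± 4576. Antigen presentation genes (7 of 26 higher, median -0.084) were not called by camera (adjusted p = 0.134). Against LF 3 and LF 4 alone, the interferon and antigen presentation medians were -0.54 and -0.56 (camera adjusted p = 1.50e-24 and 7.86e-24). Against LF 1 and LF 2 alone they were 0.28 and 0.42 (camera adjusted p = 7.12e-05 and 3.54e-07). The p values against single LF pairs use the preset correlation, since an estimated one was run only with all 8 libraries.

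**Figure D4:**
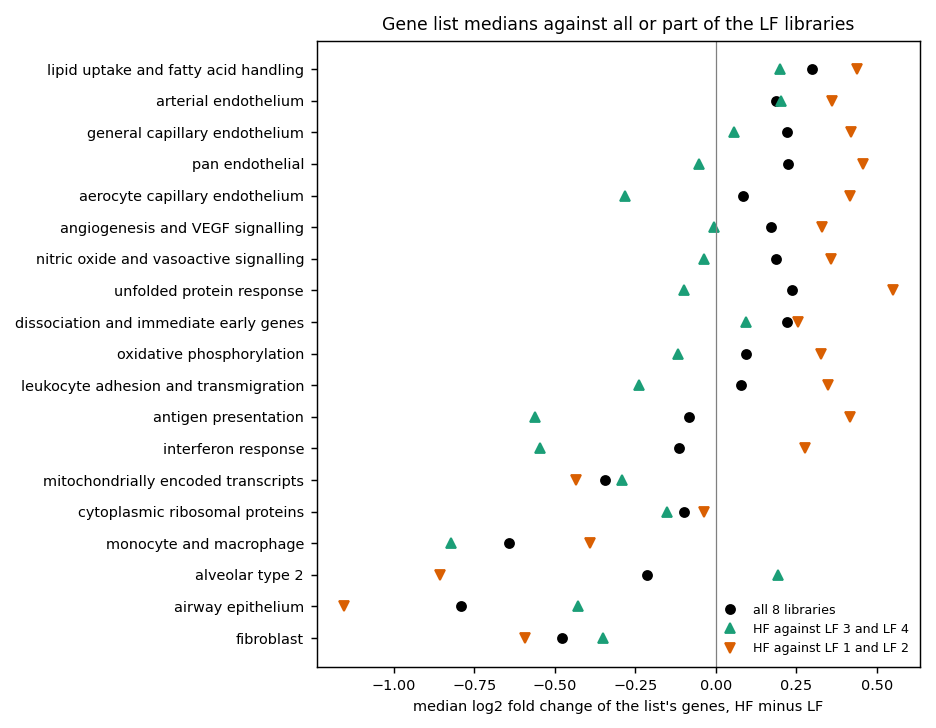
Median log2 fold change, HF minus LF, of 19 gene lists on the horizontal axis, against all 4 LF libraries (black), against LF 3 and LF 4 (green) and against LF 1 and LF 2 (orange). Fatty acid handling is above 0 in all of these comparisons (0.30, 0.20 and 0.44), while the interferon median is -0.54 against LF 3 and LF 4 and 0.28 against LF 1 and LF 2.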

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

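The tests with 1 surrogate variable, of fatty acid handling without LF 1 and LF 2 and against the pan endothelial score within each LF pair, and of the other cell types moving alike were chosen only after the results were seen. Among 180 groups of 4 values looked at (35 named genes, 48 lists and 7 library measures in each group), 8 held a library far from the others, where chance gives about 1 in 20 such groups, or 9. Each was found by the gap to its nearest neighbour as a share of the range (Dixon ratio). HF 4 was at 10.56 on the log2 scale for Tmem221, with the other HF libraries at 10.26 to 10.29, and at 9.757 for Galnt10, with the others at 9.389 to 9.43. HF 3 had a junction score of 0.00548, below 0.0657 to 0.0706 in the others, and a neutrophil score of -1.315, below -0.255 to -0.0406. HF 4 had a coagulation score of -0.08395, below 0.0211 to 0.0320. HF 1 had a fatty acid handling score of 0.101, below 0.170 to 0.184, and an airway epithelium score of 0.04786, above -0.686 to -0.566. LF 1 had 10631506 reads, below 14751039 to 15516831 in the other LF libraries.

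The first pattern is that limma and edgeR called 0 genes (1882 and 1905 at an unadjusted p under 0.05) where DESeq2 called 326 and the authors' deposited table lists 311. With 1 surrogate variable, which differed most between LF 1, LF 2 and the rest, limma called 278 genes, consistent with differences among libraries that the group does not account for hiding group differences. Fits of that kind did not call genes for any grouping, since only 1 of the 35 splits of the 8 libraries, the real split, gave as many, and the highest other split gave 48. Among the genes tested, DESeq2 called 309 in the real split, but 2 of 35 splits gave as many and the highest other gave 1378, that of HF 1, HF 3, LF 1 and LF 2 against the rest, which points to a structure of the samples, so chance was not excluded for the DESeq2 count. Nor was it excluded for limma's 1882 genes at an unadjusted p under 0.05, reached by 6 of 35 splits (highest other 4562), or for the 27 lists, reached by 4 of 35 (highest other 31), while the 0 adjusted calls are reached by 35 of 35 splits by construction (highest other 3), which says nothing about chance.

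The second pattern is the fatty acid handling list higher in HF. Deeper sequencing of the HF libraries and GC content or gene length are argued against, since the median log2 fold change was 0.29 with reads thinned to the lowest library and 0.30 with GC content and exon length regressed out, beside 0.30, and camera kept its call (adjusted p = 3.27e-07 and 1.95e-06). LF replicates 1 and 2 alone are argued against as the source, since the median was 0.20 without them (camera adjusted p = 0.00679), while chance stays open: 1 of 35 splits, the real split, gave a list test as extreme (-log10 p of 8.13, highest other 6.40), but the list was picked from 48 for its result in that split, and its exact permutation p was 0.305 after Benjamini-Hochberg adjustment over the lists. Over all LF libraries dilution of endothelial RNA stays open, with the list's score minus the pan endothelial score higher in HF by 0.094 (exact two-sided permutation p = 0.229); the prediction written beforehand counted any p of 0.05 or more for dilution, and the reading as undecided, since a missed threshold with 4 against 4 libraries does not show equality, was adopted only after the result was seen. Against LF 3 and LF 4, that difference was 0.18 (standard error 0.043 over libraries, 4 HF and only 2 LF). It exceeds 2 standard errors, the rule used, which argues against dilution as the whole cause there, though on few libraries. Against LF 1 and LF 2 the difference was 0.0063 (standard error 0.037), with the fatty acid and pan endothelial scores higher in HF by 0.43 and 0.43. Dilution there would give this equality, but the equality is not specific to it. Lists not particular to endothelium had higher medians in HF there too (unfolded protein response 0.55, heat shock 0.53, oxidative phosphorylation 0.33). Mitochondrially encoded (-0.43) and cytoplasmic ribosomal protein genes (-0.037) did not.

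The third pattern is the lower level of other cell types' markers in HF, from cells that the gate for CD31 without CD45 should have removed. A single share of other cells that moves all types alike is argued against, for HF against each LF pair. Erythrocyte scores of LF 1 and LF 2 (-0.191 and -0.322) lay within the HF range (-0.537 to 0.0185), and those of LF 3 and LF 4 above it (0.838 and 0.597). For alveolar type 2, LF 1 and LF 2 lay above the HF range (0.232 and 1.001, HF -0.408 to 0.181), while LF 3 and LF 4 did not (-0.688 and 0.0246). From LF 3 to LF 2, both LF, the monocyte and macrophage list moved by -1.15 (standard error 0.24 over 23 genes) and the alveolar type 2 list by 1.69 (standard error 0.28 over 17 genes). These comparisons were chosen after the scores were seen, and standard errors over genes do not measure the spread between libraries. Airway, fibroblast, pericyte and smooth muscle, macrophage, neutrophil and lymphocyte calls were kept against both pairs. Deeper sequencing of the HF libraries is argued against too, since 10 of the 10 calls were kept after thinning, and LF replicates 1 and 2 do not account for all of it, since 7 of 10 calls were kept without them, though medians shrank for airway epithelium (-0.79 to -0.43), pericytes and smooth muscle (-0.34 to -0.17) and alveolar type 1 (-0.28 to -0.083). Different carried-over cells or free RNA in each sort, and a change of these cells in HF lungs, stay open and were not told apart here. Abundant transcripts among these were Hbb-bs at 8738 in HF and 12004 in LF and Sftpc at 5805 and 6628.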

How the results depend on the processing

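The fits that leave out pairs of LF libraries, add a surrogate variable, thin reads or regress out GC content and exon length, and all alternatives for the count at an unadjusted p, were chosen after the data were seen. limma's 0 adjusted calls, beside 1882 at an unadjusted p under 0.05, were also found with both other pseudocounts, the stricter filter, quantile and TMM scaling, array weights, robust moderation, a threshold of 0.10, thinning, the GC and length regression and edgeR (1905 unadjusted). Counts below are of genes changed, then of genes higher in HF and genes lower in HF, and unadjusted stands for genes at an unadjusted p under 0.05. DESeq2 called 326 (253 and 73). Without a filter limma called 1, Inhbb (adjusted p = 0.0256), with 1 higher, 0 lower and 2880 unadjusted. Leaving out each library in turn gave 0 to 1 genes, 0 to 1 higher and 0 to 1 lower (Lilr4b without LF 2, Lipe without LF 4, chosen after their values were seen), 1142 (without HF 4) to 3099 (without LF 4) unadjusted and 23 to 28 lists. Without LF 1 and LF 2, limma called 641 (528 higher, 113 lower), edgeR 713 (602 and 111) and DESeq2 972 (775 and 197). Without LF 3 and LF 4, limma called 3421 (2393 and 1028), with 6280 unadjusted. With 1 surrogate variable it called 278 (241 and 37), of which 161 are among the 311 of the authors' deposited table. The replicate numbers did not pair the libraries (correlations of same-numbered libraries -0.22 to 0.18, 2 of 8 best with their own number), and the replicate block gave 0 genes, 1810 unadjusted and 29 lists, including all 27. Camera's 27 lists became 0 with an estimated correlation and 0 with fry, and 20 to 31 in the other alternatives. The totals include new calls: of the 13 higher and 14 lower lists, 5 and 14 were kept with a mean of at least 50, 5 and 14 with quantile normalisation, 5 and 10 without LF 1 and LF 2, and 6 and 10 with the surrogate variable. Among lists called in the main test or in the alternative, the direction of the test turned (medians in brackets) for oxidative phosphorylation with quantile normalisation (-0.0080), without LF 1 and LF 2 (-0.12) and with the surrogate variable (-0.049), and its median ran from 0.0046 (without LF 2) to 0.20 (without LF 3) over single libraries left out, where the direction turned without LF 2. Interferon response ran from -0.34 (without LF 1) to 0.073 (without LF 4, where the direction turned). Without LF 1 and LF 2 it turned for the unfolded protein response (-0.0995), heat shock (-0.16), pan endothelial (-0.052), aerocyte (-0.28) and alveolar type 2 markers (0.19), and without LF 3 and LF 4 for leukocyte adhesion (0.35, beside a median of 0.08 whose test was lower), interferon response (0.28) and antigen presentation (0.42). The aerocyte direction also turned with the surrogate variable (-0.19). Of 908 values of 35 named genes under alternatives, 49 changed sign. The cause was not tested, except that fewer libraries enter the fits that leave some out.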

Other observations

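Several lists outside the main account are given here as values. Clock genes had the higher mean in HF in 13 of 19 (median log2 fold change 0.19, camera adjusted p = 0.104), led by Nr1d2, a repressor of the clock, at 850.0 ± 159 in HF and 527 ± 63.5 in LF, and by Per1 at 483 ± 115 against 334 ± 43.1. Without LF 1 and LF 2, camera called the clock list higher in HF (median 0.26, adjusted p = 0.00588), and without LF 3 and LF 4 it did not (median 0.022, adjusted p = 0.989, with the test's direction lower). Cell cycle genes had the lower mean in HF in 21 of 38 (median -0.064, camera adjusted p = 0.113), with Birc5 at 16.5 ± 5.22 against 31.7 ± 3.12. In the glycocalyx list (15 of 23 higher, camera adjusted p = 0.356), the syndecan Sdc3 was at 2204 ± 737 against 1228 ± 91.5 and the sulfotransferase Ndst2 at 853 ± 120 against 577 ± 67.8. In the coagulation list (14 of 26 higher, median 0.051 with a mean of -0.0039, camera adjusted p = 0.968), the plasminogen activator Plat was at 10304 ± 694 against 5772 ± 1942. The NF-kB list (15 of 30 higher, camera adjusted p = 0.616) was called lower without LF 1 and LF 2 (median -0.24, camera adjusted p = 0.00400) and not called without LF 3 and LF 4 (median 0.22, camera adjusted p = 0.0976). In it, Cebpd was at 7212 ± 1311 against 3678 ± 1347 and Ptgs2 at 625 ± 151 against 849 ± 84.2.

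Further lists were not called by camera in the main test: cholesterol synthesis (median 0.062, adjusted p = 0.595), glycolysis (median 0.11, adjusted p = 0.306), basement membrane (median -0.053, adjusted p = 0.674), TGF-beta response (median -0.098, adjusted p = 0.221), MYC and ribosome biogenesis (median 0.055, adjusted p = 0.516), adipocyte markers (median 0.44 over 5 genes, adjusted p = 0.133) and cardiomyocyte markers (median -0.045 over 5 genes, adjusted p = 0.262). Glycolysis was called higher without LF 3 and LF 4 (median 0.25, camera adjusted p = 0.00858) and not called without LF 1 and LF 2 (median -0.028, camera adjusted p = 0.160). Adipocyte markers were called higher with quantile normalisation (median 0.36, camera adjusted p = 0.0372).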
